A study of Mus musculus with 4 samples.

How the data were processed

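The samples were P14 CD8+ T cells from mouse spleen that carried an empty vector or a Hic1 overexpression vector, with 2 libraries per group. Per the labels' protocols, 5000 cells of each kind were sorted, 1000 were resorted into lysis buffer, and polyadenylated RNA from 5 µl of lysate was made into Smart-seq2 libraries with 12 cycles of PCR after fragmentation. The deposited raw table holds read counts per gene and library as whole numbers, with no scaling seen in the values. Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.5.2b, featureCounts 1.5.3, DESeq2 1.3.2 and the genome mm10 were used, with no role or order stated. The annotation release and the read layout are not given in the sources used here. The deposited normalized table holds a signal that equals the raw count divided by a single factor per library, plus 1, as learned from its values. Those factors (0.7347, 0.7155, 1.258 and 1.556) match DESeq2 size factors computed on all genes, and the normalized table was used for nothing else.

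Tests used the 55401 genes of the raw table. Gene identifiers were joined to GENCODE M21, where 98.1% of them were found, for transcript length and GC content, and coordinates are given only where the identifier's version matched. Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 11676. Counts were scaled by TMM and fitted by group alone with edgeR's quasi-likelihood F test (robust, prior count 2 for log2 fold changes). Genes were called at a Benjamini-Hochberg adjusted p below 0.05. CPM values use TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation preset at 0.01, over the 28 of 36 lists with at least 5 tested members, apart from the list of sex-linked genes. Hic1 was left out of every list. Where camera estimates the correlation instead, it uses the residual degrees of freedom, which are few with 2 libraries per group. That version could hardly pass any list here, so its lack of calls decides neither for nor against a list. Other versions were R 4.3.3, DESeq2 1.42.0, scipy 1.17.1 and matplotlib 3.10.9.

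The comparison, the tests, the 36 lists, 16 alternatives for gene tests and the naming rule were fixed before the data were examined. The rule names Hic1, the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean of at least 5 CPM and no overlap between the groups (81 higher and 117 lower met this), and in each list up to 4 members of lowest p. Any member of the residency, recirculation, gut homing and Hic1 target lists could also be named. Xist and Eif2s3y come from the list of sex-linked genes, and predicted genes and pseudogenes were counted but not named. Genes named outside the rule are Art2b and Slc17a9, the genes of the T cell receptor and of the replicate numbers, which were chosen after the data were seen. Another 5 alternatives for gene tests were also added then: GC correction, length correction, GC correction with a replicate block, and omission of ribosomal RNA and repeat genes or of X and Y genes. The corrections removed a loess trend (span 0.3) from each library.

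The libraries held 20748, 20808, 21597 and 23631 genes with a count, in the order empty vector 1 and 2 and Hic1 vector 1 and 2. A single ribosomal RNA gene, CT010467.1, took 5.16%, 8.38%, 13.4% and 8.35% of the counts. Between libraries of a group, the chi-square per degree of freedom was 10.5 for the empty vector and 22.7 for the Hic1 vector, so the spread was above counting error, and the Pearson correlation of log2 CPM was 0.958 and 0.966. The common biological coefficient of variation was 0.195. Reads from PCR without molecular identifiers are not independent molecules, so counting intervals cover counting error only. The test was tested on simulated data with the same depths. It recovered 42 of 97 genes with a 2-fold change and 83 of 93 with a 4-fold change. It made 13 false calls there, a larger share of the calls than the threshold of 0.05 aims at, and 1 call when no gene was changed. The simulated counts held no effect of the replicate number, no GC trend and no correlation between genes, so they are simpler than these data.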

Results

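Messenger RNA was sequenced from mouse P14 CD8+ T cells, which carry a transgenic T cell receptor specific for lymphocytic choriomeningitis virus (LCMV). The cells had received either a control vector without an insert or a vector that overexpresses Hic1, a zinc finger transcriptional repressor, and were taken from the spleen after infection with the Armstrong strain. The sample labels give day 32 after infection and the series text gives day 7, so the time point is stated here both ways. There were 4 libraries in 2 groups, empty vector replicates 1 and 2 and Hic1 vector replicates 1 and 2 (n = 2 per group). Each was made by Smart-seq2 from 5 µl of lysate of about 1000 resorted cells. Total gene counts were 4017346 and 3941364 for the empty vector libraries and 7501285 and 8839317 for the Hic1 vector libraries, so depth differed with the group. The labels do not say whether the replicates came from separate mice, and p-values therefore measure the spread between these samples. Xist, the long non-coding RNA of the inactive X chromosome, had 1885 counts in empty vector replicate 1 and 3590 in Hic1 vector replicate 1, against 0 and 3 in the replicates numbered 2. The Y-linked gene Eif2s3y showed the converse, with 396 and 951 counts in the replicates numbered 2 and 0 in those numbered 1. Replicates numbered 1 thus had the sex-linked transcripts of female cells and those numbered 2 of male cells. The replicates of a group therefore did not come from the same animal. The spread between them was not technical alone, and sex is mixed into it. Differences taken within each replicate number are therefore given beside the main genes below. The main fit ignores the replicate number, so the difference between the replicates of a group adds to its spread. Where a gene is said below not to pass, that holds for this fit. With the number as a block more genes passed, 794 against 213.

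The comparison asks which transcripts change in these T cells when Hic1 is overexpressed. Hic1 itself (chromosome 11, positions 75164565 to 75169519, minus strand, mm10) had 3 and 5 counts in the empty vector libraries and 314 and 161 in the Hic1 vector libraries. Its level was 0.989 ± 0.368 CPM against 31.3 ± 18.3 CPM (SD, n = 2 each), a log2 fold change of 4.58 ± 0.586 (SE). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes the adjusted p was 0.00706. Within replicate number 1 the log2 difference was 5.39, and within number 2 it was 3.56. Counts per gene do not separate vector-derived from endogenous Hic1 transcripts. Without empty vector replicate 1 the log2 fold change was 4.34, and Hic1 was not called. Leaving out empty vector replicate 2 also leaves 1 library in the empty vector group, and Hic1 was still called then. Group size alone thus does not explain the lost call, and its cause was not tested. Over the single omissions the log2 fold change was 3.81 to 5.02, so a large difference remained whichever library was left out. With all libraries, both Hic1 vector libraries lay above both empty vector libraries.

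Besides Hic1, the Hic1 vector libraries had more P2rx7, Tcf7, Ltb, Cxcr3 and Cxcr6 RNA and less Panx1, Anxa1, Tbx21, Entpd1 and Havcr2 RNA. P2rx7, the ATP-gated receptor channel, rose by 4.51 ± 0.467 on the log2 scale (SE, n = 2 per group), which is 22.8-fold. Tcf7, the transcription factor of naive and stem-like T cells, rose 3.95-fold (1.98 ± 0.211). Panx1, a channel that releases ATP, fell by 2.23 on the log2 scale (SE 0.349), and Anxa1, an annexin, fell by 1.32 (SE 0.197). Of 11676 genes tested, 213 changed at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 84 higher and 129 lower with the Hic1 vector. Without empty vector replicate 1 the same test called 8 genes, 6 of them among the 213. With library sizes alone as the scaling, 70 genes were higher and 251 lower, which moved the share of higher genes from 39.4% to 21.8%. The genes that rose had a median transcript GC content of 55.8% and those that fell 46.1%, against 49% for all genes tested. After a GC trend was removed from each library, a correction chosen after the data were seen, 117 genes passed, 103 of them among the 213.

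The 12 named genes with the largest rises, Hic1 and P2rx7 included, spanned several functions. P2rx7 (chromosome 5, positions 122643911 to 122691432) was at 1.46 and 0.999 CPM in the empty vector libraries and at 45.5 and 25.3 CPM in the Hic1 vector libraries, with log2 differences of 4.68 and 4.26 within replicate numbers 1 and 2. Asb2, the substrate-recognition subunit of a ubiquitin ligase, rose by 3.38 ± 0.595 (log2, SE), from 1.36 ± 0.899 to 17.3 ± 9.35 CPM (SD, n = 2). Trat1, an adaptor that stabilises the T cell receptor complex, rose by 2.65 ± 0.499, from 2.44 ± 1.69 to 17.1 ± 5.47 CPM. Ncf1, a subunit of the phagocyte NADPH oxidase, rose by 2.44 ± 0.324, from 6.68 ± 2.57 to 37.6 ± 4.1 CPM. Tcf7 rose from 22.7 ± 3.89 to 90.9 ± 9.81 CPM, with log2 differences of 1.93 and 2.05 within the replicate numbers. Cpne7, a copine, rose by 2.71 on the log2 scale, Ckb, a creatine kinase, by 2.52, and Cd320, the transcobalamin receptor, by 2.06. Actn2, an actinin, rose by 2.04, Acoxl, an acyl-CoA oxidase-like gene, by 1.99, and Tnfrsf25, a death-domain receptor of the TNF family, by 1.95. Without empty vector replicate 1, P2rx7, Tcf7 and Actn2 still passed and the other 9 of the 12 did not. The remaining single omissions left 9 of 12 without empty vector replicate 2, 11 of 12 without Hic1 vector replicate 1 and 9 of 12 without Hic1 vector replicate 2. After GC correction 8 of the 12 stayed called, and Cpne7, Cd320, Actn2 and Tnfrsf25 did not, with log2 values that moved little, to 2.52, 2.02, 1.87 and 1.76.

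The 12 named genes with the largest falls, chosen among genes without overlap between the groups, included Micu2, Panx1 and Eif3f. Micu2, a regulator of the mitochondrial calcium uniporter (chromosome 14, positions 57916261 to 57999262), fell by 2.02 on the log2 scale (SE 0.241), from 116.2 ± 41 to 28.4 ± 1.74 CPM (SD, n = 2). Its log2 differences were -2.40 within replicate number 1 and -1.55 within number 2. Panx1 (chromosome 9, positions 15002128 to 15045478) fell from 87.5 ± 46.4 to 18.4 ± 1.85 CPM. Rnf168, a ubiquitin ligase of the DNA damage response, fell by 2.12 (SE 0.304), from 32.6 ± 1.6 to 7.3 ± 1.62 CPM. Tmprss13, a membrane serine protease, fell by 1.97 (SE 0.278), from 51 ± 6.1 to 12.7 ± 4.25 CPM. Eif3f, a translation initiation factor subunit, fell by 1.82 (SE 0.24), from 672.6 ± 93.4 to 190.5 ± 68.6 CPM, and Lsm4, a U6 RNA-binding protein, fell by 1.89 (SE 0.308). Hacd2, an enzyme of very long chain fatty acid synthesis, fell by 1.87. Tmem151a fell by 2.57, Phactr2 5.67-fold and Ppfibp1 by 2.22, and Fam129b and Chil5 by 2.12 and 1.82. Micu2 was the only 1 of these 12 that passed without empty vector replicate 1. Leaving out empty vector replicate 2 kept 9 of the 12, and leaving out either Hic1 vector library kept 10. After GC correction all but Chil5 (log2 value -1.74) stayed called.

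**Figure D1:**
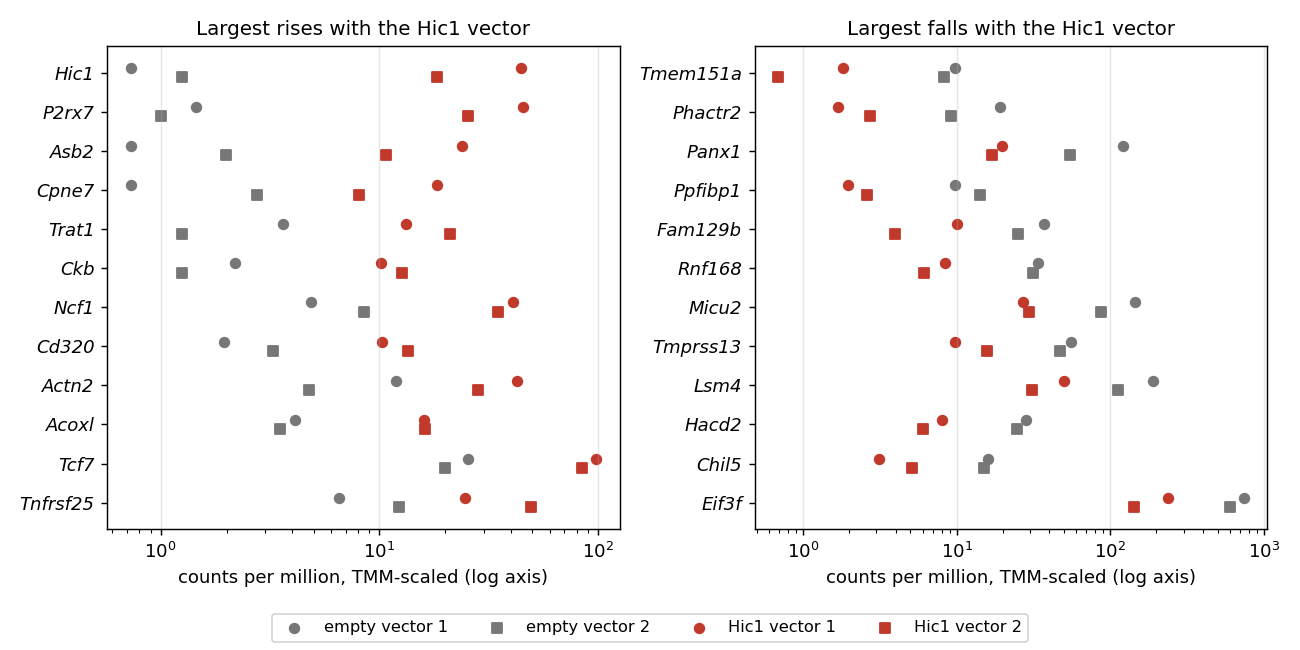
CPM scaled by TMM (log axis) of the 12 named genes with the largest rises (left) and the 12 with the largest falls (right), 1 point per library, grey for empty vector, red for Hic1 vector, circles for replicate 1 and squares for replicate 2. Genes were chosen so that the groups do not overlap; P2rx7 moves from 1.46 and 0.999 to 45.5 and 25.3 CPM.

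Among memory precursor genes Tcf7, Ltb and Cxcr3 rose with the Hic1 vector, and among terminal effector genes Anxa1 and Tbx21 fell. Of 22 memory precursor genes tested, 3 rose, none fell and 19 did not pass. When adjusted over the list alone, 5 of the 22 were higher, the same 3 genes and Il7r among them, and 2 were lower. Ltb, which encodes lymphotoxin beta, rose by 1.24 ± 0.164 on the log2 scale (SE), from 135.5 ± 19.7 to 320.6 ± 48.1 CPM (SD, n = 2). Cxcr3, a receptor for interferon-induced chemokines, rose by 1.14 ± 0.166. Il7r, the interleukin 7 receptor chain, was at 40.6 ± 7.88 against 133.6 ± 71.7 CPM and did not pass over all genes. Of 24 terminal effector genes, 2 fell, none rose and 22 did not pass, and 20 of the 24 had a fold change below 0. Anxa1 fell from 321.3 ± 80.5 to 128.3 ± 24 CPM, and Tbx21, which encodes the effector transcription factor T-bet, fell by 0.84 (SE 0.17). Zeb2, a repressor found in effector cells, and S100a4 had log2 values of -0.65 ± 0.165 and -0.64 ± 0.166 and did not pass over all genes. Over the list alone, 9 terminal effector genes were called, 8 of them lower. As lists, camera with a preset correlation passed the terminal effector genes (median -0.27, adjusted p = 0.000161) and the memory precursor genes (median 0.33, adjusted p = 0.0107). Neither passed with the correlation estimated from the data (adjusted p = 0.826 with an estimated correlation for both). The estimate was 0.193 for memory precursor genes but -0.0124 for terminal effector genes, below the preset 0.01. The lost pass of the terminal effector list thus did not come from a higher correlation value. An estimate from so few libraries is rough and does not show that the genes of the list are uncorrelated. With so few libraries the version with an estimated correlation could hardly pass any list, so it decides nothing here. With 1 library left out, the median was -0.294 to -0.23 for terminal effector genes and 0.148 to 0.467 for memory precursor genes. By camera the memory precursor list also missed the threshold without empty vector replicate 2 (adjusted p = 0.147) and without Hic1 vector replicate 1 (adjusted p = 0.0678). Without empty vector replicate 1, Tcf7 alone among these 5 called genes still passed.

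Among tissue residency genes P2rx7 and Cxcr6 rose and Runx3 fell, and among recirculation genes Tcf7 rose. Of 28 residency genes tested, 2 rose (P2rx7 and Cxcr6), 1 fell (Runx3) and 25 did not pass. Cxcr6, a chemokine receptor of resident T cells, rose by 0.68 ± 0.122 (log2, SE), from 603.1 ± 25.5 to 964.2 ± 70 CPM (SD, n = 2). Runx3, a transcription factor of the CD8 lineage and of residency, fell by 0.71 (SE 0.158), from 236.5 ± 38.7 to 144.6 ± 7.22 CPM. Itgae, the integrin chain CD103, was at 8.24 ± 1.05 against 12.1 ± 4.75 CPM, and Cd69 had a log2 value of 0.16 ± 0.633; neither passed. Itgb1, the integrin beta 1 chain, was at 1590 ± 709.1 against 377.8 ± 133.9 CPM and did not pass, though DESeq2 (adjusted p = 0.0169) and limma voom (adjusted p = 0.0206) called it. When adjusted over the list alone, 7 residency genes were higher and 2 lower. Of 23 recirculation genes, Tcf7 rose, none fell and 22 did not pass, with 4 higher and 7 lower when adjusted over the list alone. S1pr1, the sphingosine 1-phosphate receptor for tissue exit, was at 429.7 ± 19 against 370.4 ± 4.92 CPM, Ly6c2 had a log2 value of -0.84 ± 0.201 and S1pr4 one of 0.58 ± 0.146, and none of these passed over all genes. Camera with a preset correlation gave an adjusted p of 0.368 for the residency list and 0.391 for the recirculation list. Residency passed camera without empty vector replicate 1 (adjusted p = 0.0472) and without Hic1 vector replicate 2 (0.00416), and recirculation, in the downward direction, without Hic1 vector replicate 2 (0.0242). With all libraries these lists gave adjusted p = 0.914 and 0.826 with an estimated correlation in camera. Of the 4 calls named in these 2 lists, P2rx7 and Tcf7 passed without empty vector replicate 1.

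Gut homing and retinoic acid genes, and genes of intestinal intraepithelial lymphocytes, did not pass camera, which tests for a shared direction. Of 13 gut homing and retinoic acid genes tested, P2rx7 rose, none fell and 12 did not pass, with 2 higher and 4 lower when adjusted over the list alone. Itgb7, the beta 7 integrin chain of gut homing, had a log2 value of -1.13 ± 0.223 (SE, n = 2 per group) and its partner Itga4 one of -0.36 ± 0.115. Ccr9, the gut homing chemokine receptor, was at 3.29 ± 2.89 against 17.7 ± 5.76 CPM, and like Itgb7 had an adjusted p of 0.0544 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Itgb7 was called in 14 of 20 alternatives and Ccr9 in 8 of 20, both after GC correction among others. This list had a median of -0.12, a mean of 0.17 and a camera direction of down (adjusted p = 0.412), so the mean and the other measures differ in sign. Of 18 intraepithelial lymphocyte genes, Cd160 and Lag3 rose, none fell and 16 did not pass (of all 18, 4 higher and 2 lower over the list alone; camera adjusted p = 0.383, up). Cd160, a receptor of cytotoxic and intraepithelial T cells, rose by 1.05 ± 0.164 and Lag3, an inhibitory receptor, by 0.89 ± 0.175. Neither of these passed without empty vector replicate 1, and Lag3 was not called after GC correction (0.69). None of 6 tested genes that the literature names as Hic1 targets passed over all genes, 1 (Gadd45b, 16.7 ± 3.3 against 32.6 ± 9.74 CPM) was higher over the list alone, and the list gave a camera adjusted p of 0.408.

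Camera with a preset correlation passed the interferon-stimulated genes (median 0.46, adjusted p = 9e-05), the T cell receptor signalling genes (median 0.21, adjusted p = 0.0222) and the NK receptor genes (median 0.31, adjusted p = 0.0222), all upward. None of these 3 passed with the correlation estimated from the data (adjusted p = 0.826 with an estimated correlation for each). As above, that version could hardly pass any list with so few libraries. Of 35 interferon-stimulated genes tested, Bst2 and Slfn1 rose, none fell and 33 did not pass, while 10 were called, all higher, when adjusted over the list alone. Bst2, which encodes the antiviral protein tetherin, rose by 1.02 ± 0.192 (log2, SE), from 34.1 ± 0.173 to 69.6 ± 0.231 CPM (SD, n = 2), and Slfn1, a schlafen gene, rose by 0.67 ± 0.147. Oas3 and Gbp3 had log2 values of 0.66 ± 0.179 and 0.68 ± 0.193 and did not pass over all genes. Of 29 T cell receptor signalling genes, Trat1 and Zap70 rose and 27 did not pass, with 8 higher and 1 lower when adjusted over the list alone. Zap70, the proximal tyrosine kinase, rose by 0.66 ± 0.14 but was not called after GC correction (0.46, adjusted p = 0.145 by the same edgeR test), and Bst2 was not called then either (0.85), while Cd6 and Plcg1 had log2 values of 0.70 ± 0.167 and -0.57 ± 0.155 and did not pass. Of 20 NK receptor and innate-like genes, Cd160 and Klra8 rose and 18 did not pass, with 8 higher and 3 lower when adjusted over the list alone. Klra8, which encodes the receptor Ly49H, had 2 and 1 counts in the empty vector libraries and 78 and 48 in the Hic1 vector libraries. The ratio of pooled rates was 21.5 (95% exact counting interval 7.19 to 105.6), and that interval leaves out the spread between libraries. The log2 fold change of Klra8 by edgeR was 3.60 ± 0.768 (SE), which is 12.1-fold. The Klra genes are close paralogs and reads shared among them were not resolved here, so values such as the 1.60 ± 0.141 against 7.14 ± 0.262 CPM of Klra9 are uncertain. The T cell receptor list was not called without Hic1 vector replicate 2 (adjusted p = 0.145), nor the NK receptor list without empty vector replicate 2 (0.113). Bst2, Slfn1, Trat1, Zap70, Cd160 and Klra8 all lost their calls without empty vector replicate 1, and both interferon genes also without empty vector replicate 2 or Hic1 vector replicate 2. The median of the interferon-stimulated list stayed above 0, at 0.242 to 0.534, whichever single library was left out.

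**Figure D2:**
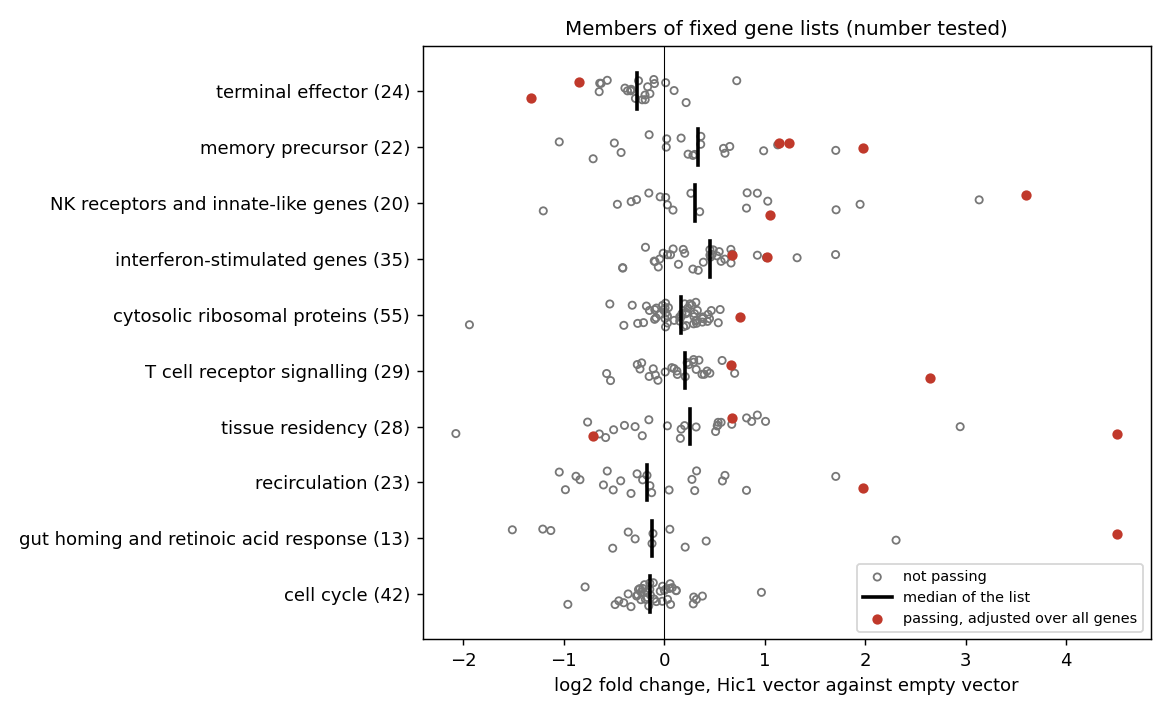
Log2 fold change (Hic1 vector against empty vector, n = 2 each) of each tested member of 10 gene lists fixed before the data were examined, 1 point per gene, filled red where the gene passed over all genes tested, with a black bar at the list's median. The median is 0.46 for interferon-stimulated genes, 0.33 for memory precursor genes and -0.27 for terminal effector genes.

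Inhibitory receptor genes split, with Cd160 and Lag3 higher and Entpd1 and Havcr2 lower among 19 tested, and 15 not passing. When adjusted over the list alone, 6 of the 19 were higher and 3 lower, these 4 included. Entpd1, the ectonucleotidase CD39, fell by 1.25 (SE 0.199), from 128 ± 20 to 53.5 ± 12.6 CPM (SD, n = 2), and Havcr2, the receptor TIM-3, fell by 0.99 (SE 0.186). Camera gave this list an adjusted p of 0.323 (up), and 0.0242 without Hic1 vector replicate 2 (with all libraries, adjusted p = 0.88 with an estimated correlation). Of 32 chemokine receptor and integrin genes, Cxcr3, Cxcr6 and Selplg rose, none fell and 29 did not pass, with 6 higher and 4 lower over the list alone. Selplg, the selectin ligand PSGL-1, rose by 0.55 ± 0.115. The median of that list was -0.04 and its camera direction up, so these differ in sign (adjusted p = 0.91). Of 19 TGF-beta response genes, Smad3 and Tgfbr2 fell and 17 did not pass, and the same 2 genes were the calls over the list alone (camera adjusted p = 0.171, down). Smad3, a signal transducer of the pathway, fell by 0.84 (SE 0.18) and Tgfbr2, its type 2 receptor, by 0.73 (SE 0.157). Of 34 cytokine receptor and STAT signalling genes, Il18r1 and Il6ra fell and 32 did not pass, with 2 higher and 5 lower over the list alone. Il18r1, the interleukin 18 receptor, fell by 1.19 (SE 0.233), Il6ra fell by 2.54 (SE 0.684), and Jak3 and Jak1 had log2 values of 0.62 ± 0.147 and -0.46 ± 0.118 that did not pass. That list had a median of 0.06 and a mean of -0.02 (camera adjusted p = 0.898, up). Of 23 cytotoxic mediator and cytokine genes none passed over all genes, with Ctsw higher and Lamp1 lower over the list alone, a median of -0.03, a mean of 0.03 and a camera adjusted p of 0.765 (up). Without empty vector replicate 1 none of the calls named for these lists passed, and after GC correction Lag3, Havcr2, Tgfbr2, Il18r1 and Il6ra did not, at log2 values of 0.69, -0.86, -0.69, -1.04 and -2.53.

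Camera with a preset correlation passed the cytosolic ribosomal protein genes (up, median 0.17, adjusted p = 0.00212), but not with the correlation estimated (adjusted p = 0.826 with an estimated correlation). Of 55 ribosomal protein genes tested, Rpl18 rose by 0.76 ± 0.132 (log2, SE, n = 2 per group), none fell and 54 did not pass, with 7 higher and 1 lower when adjusted over the list alone. Rps18 was at 293 ± 10.2 against 431.4 ± 2.78 CPM. Rps2 was at 387.6 ± 145 against 101.1 ± 39.4 CPM and did not pass over all genes, though 11 of 20 alternatives called it; reads shared with pseudogenes were not examined here. By camera the list did not pass without empty vector replicate 2 (adjusted p = 0.173) or Hic1 vector replicate 2 (adjusted p = 0.238), and Rpl18 was not called without empty vector replicate 1. None of 8 mitochondrially encoded transcripts passed over all genes, 1 of them, mt-Nd2, was higher over the list alone (0.67 ± 0.159), and the camera adjusted p was 0.383. That list passed camera after the GC correction (adjusted p = 0.00311), as mt-Nd2 did by edgeR, while the list without the correction gave adjusted p = 0.826 with an estimated correlation. Of 20 fatty acid genes, Acsl4, an acyl-CoA synthetase, fell by 0.95 (SE 0.206) and 19 did not pass, with 1 higher and 1 lower over the list alone (camera adjusted p = 0.171, up), and Acsl4 was not called without empty vector replicate 1 or after GC correction (-0.74). No gene passed, over all genes or over the list alone, among 54 oxidative phosphorylation genes (camera adjusted p = 0.171, up), 23 glycolysis and hypoxia genes (0.171, up), 20 cholesterol synthesis genes (0.85, up), 22 p53 targets (0.898, down) or 42 cell cycle genes (0.171, down). The cell cycle list gave camera adjusted p values of 0.0044 and 2.72e-08, both down, without empty vector replicate 2 and without Hic1 vector replicate 1, and 0.0424, up, without Hic1 vector replicate 2. With all libraries it gave adjusted p = 0.914 with an estimated correlation in camera. Oxidative phosphorylation passed without empty vector replicate 1 (0.0313) and without Hic1 vector replicate 1 (0.0344). With all libraries, camera gave adjusted p = 0.88 with an estimated correlation for this list. Of 22 immediate early and stress genes none passed over all genes, Junb (0.73 ± 0.167) was higher over the list alone, and the camera adjusted p was 0.383 (up) with all libraries and 0.0179 without Hic1 vector replicate 2 (with all libraries, adjusted p = 0.826 with an estimated correlation).

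Among markers of other cell types Ighm, Klra8 and Bst2 rose and none fell. Of 6 tested B cell genes, Ighm, the IgM heavy chain gene, rose by 1.57 ± 0.186 (log2, SE), from 72.9 ± 16.3 to 217.5 ± 28.9 CPM (SD, n = 2), and it passed whichever single library was left out. The other 5 did not pass, among them Cd79b at 9.76 ± 9.2 against 25.7 ± 17.5 CPM and Igkc at 5.2 ± 2.54 against 2.75 ± 1.1 CPM (camera adjusted p = 0.171, up; 1 call over the list alone). Of 10 NK cell markers, Klra8 rose and 9 did not pass, with 3 higher and 3 lower over the list alone, and of 4 dendritic cell markers, Bst2, also an interferon-stimulated gene, rose and 3 did not pass. The NK cell markers had a median of -0.03, a mean of 0.36 and a camera adjusted p of 0.898 (up). None of 5 macrophage and monocyte genes passed (median 0.07, mean -0.28, camera adjusted p = 0.898, up), nor did any of 5 CD4 and regulatory T cell genes (0.898, up), with no call over either list alone. No marker passed over all genes among 2 plasma cell, 2 erythroid, 1 platelet, 1 stromal and endothelial and 3 gamma delta and MAIT T cell genes tested. Over each list alone 1 plasma cell gene was lower and 1 erythroid and 1 platelet gene were higher. None of the neutrophil markers reached the count minimum for testing.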

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

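Beside Hic1, the 47 named genes that passed, Art2b and Slc17a9 included, kept their direction in all 937 alternative values and lost the call in 175; of 1536 values for 77 named genes, 4 reversed. Of 276 alternative values for 28 lists 22 reversed, none among the 6 lists that passed, which lost the call in 18 of 60. Alternatives chosen after the data were seen were the GC and length corrections, the GC correction with a replicate block, and the omission of ribosomal RNA and repeat genes (204 genes changed) or X and Y genes (213). Against 213 genes changed (84 higher, 129 lower), counts were 321 (70 and 251) with library size only, 819 (461 and 358) without the filter, 418 (152 and 266) with DESeq2, 121 (33 and 88) with limma voom, 140 (47 and 93) without robust estimation, 152 (54 and 98) after thinning, 117 (38 and 79) after GC correction and 119 (55 and 64) after length correction; the cause was not tested. A required absolute log2 fold change of at least 1 left 136 (43 and 93) by construction. Leaving out 1 library gave 8 to 318 genes changed, 6 to 87 higher and 2 to 232 lower (78 without Hic1 vector replicate 2, 218 without Hic1 vector replicate 1), lowest without empty vector replicate 1; the lone library left in a group is assumed to vary like the other group. The Hic1 log2 fold change was 3.81 to 5.02 with 1 library left out, and it lost its call without empty vector replicate 1 (4.34) and with limma voom (4.68, adjusted p = 0.0784); the cause was not tested. No list passed with an estimated correlation (0) or with fry's test for a shared direction (0), against 6 by camera. Fry's mixed test, which counts changes in either direction, passed some lists and not others. Its adjusted p was 0.00644 for gut homing and retinoic acid genes, 0.0155 for chemokine receptors and integrins and 0.0576 for residency. By camera, 4 to 9 lists passed with 1 library left out.

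With the replicate number as a replicate block, 794 genes changed (378 higher, 416 lower), and 460 (174 and 286) with GC correction as well. Deviations of same-numbered libraries correlated at 0.239, but there are only 2 pairs and the labels name no shared animal, so the numbers were not taken as pairs of animals. Sex-linked transcripts split by the number in both groups, though, so the number marks sex at least, and a block for sex needs no shared animal. The main fit, fixed before the data were examined, leaves that split in its spread. The common biological coefficient of variation was 0.195 in the main fit and 0.145 with the block. The replicate block lost none of the 46 calls the naming rule gave to the text, Hic1 included. Of 30 named genes that did not pass, it called 25. Among them by edgeR with the block were Itgb1 (adjusted p = 1.6e-05), Rps2 (5.67e-05), Il7r (0.00191) and Itgb7 (0.00229). Of the same 30, limma voom called 3 (Itgb1 at 0.0206) and DESeq2 18 (Itgb1 at 0.0169). Cd69 reversed with the replicate block (-0.0075), with limma voom (-0.0744) and without empty vector replicate 2 (-0.0461), and ranged from -0.849 to 0.764 with 1 library left out.

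Camera directions reversed at the medians given, with the range of the median over libraries left out: residency -0.0121 to 0.718, reversed at the lower end; recirculation -0.346 to -0.0992 (direction reversed at -0.194); cytotoxic -0.0476 to 0.148 (reversed at -0.0476 and 0.0027); chemokine receptors and integrins -0.152 to 0.0187 (reversed at -0.152, -0.0122, -0.0432, and -0.0657 with the replicate block). The p53 targets spanned -0.202 to 0.125 (reversed at 0.125, 0.0544, and 0.0182 after GC correction), cell cycle -0.433 to 0.168 and immediate early genes -0.0441 to 0.27 (direction reversed at 0.166). Cytokine receptors spanned -0.0209 to 0.11 (reversed at -0.0209, and 0.00849 after GC correction). Among markers, B cell spanned -0.75 to 0.429, macrophage -1.12 to 0.341 (reversed at -1.12 and -0.937), NK cell -0.152 to 0.0593 (reversed at -0.152, 0.0577, and -0.037 with the replicate block), and CD4 T cell 0.0845 to 0.621 (direction reversed at 0.116). Medians alone also changed sign over libraries left out for mitochondrially encoded transcripts (-0.0232 to 0.105), oxidative phosphorylation (-0.00263 to 0.109) and cholesterol synthesis (-0.0255 to 0.139). Their cause was not tested.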

Other observations

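The receptor genes of the cells were those of a single clone in large part. Trav14-1 held 85.8% and 87.4% of T cell receptor alpha variable counts in the empty vector libraries and 89.1% and 91.8% in the Hic1 vector libraries. Trbv13-3 held 74.2% and 62.5% of beta variable counts, and 62.2% and 83.0%, in the same order. Across both groups 27 genes, sex-linked ones among them, differed with the replicate number. Ifitm1, Fos and Jun were lower in the replicates numbered 2 (log2 differences -3.03, -3.31 and -2.11), as were Dusp1 (-1.99) and Egr1 (-1.95). Itgb1 (-0.841) and Rps2 (-0.797), which had large SDs within the groups, were lower there too.

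The tests of Ighm, the GC and length corrections, the fold changes of genes that lost the call after GC correction and the share of calls kept at equal total counts were chosen only after the calls were seen. The 213 called genes were weighed against technical trends. After thinning to the smallest library the median absolute log2 fold change of the called genes fell by 0.158% and 62% stayed called, which decides nothing, since thinning leaves expected fold changes as they are and ends calls only by lowering counts. Depth and the vector cannot be told apart, since depth differed with the group. After removal of a length trend 52.1% of the called genes stayed called, and their median absolute log2 fold change fell by 2.7%. A smooth length trend thus made up little of the size of these fold changes, in genes picked for their differences in the same data. The fall does not show how many calls the trend made, and many calls were lost. After removal of a GC trend 48.4% stayed called and the median fell by 9.16%; the 110 genes that lost the call went from a median of 0.995 to 0.814, with a median SE of 0.204 before and 0.202 after, so the fold shrank and the spread did not grow. That is a fall of 18.2%, so a smooth GC trend, as removed here, made up a small part of the size of their fold changes. The genes were picked for their differences in the same data, which works against a large fall. The fall therefore does not show how many calls the trend made. All 110 also kept their sign and an unadjusted p below 0.05 (edgeR). These genes were chosen for low p in the same data, so that decides nothing. How many genes would be called without the trend stays open, since the trend with GC (Spearman rho 0.303 across genes) runs between the groups, at 0.275 and 0.236 within replicate numbers 1 and 2.

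Ighm was higher in the Hic1 vector libraries, and RNA from B cells was weighed as the source. Igkc counts were at most 1.79% of Ighm counts there, and Igkc was at 1.97 and 3.53 CPM, which argues against B or plasma cells. No other explanation was tested.

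Genes of extracellular ATP and NAD handling drew attention among the calls: P2rx7 (4.51 ± 0.467, log2, SE), Art2b (1.47 ± 0.185) and Slc17a9 (1.16 ± 0.213) rose, and Panx1 and Entpd1 fell. Of 23 other family members tested, 5 (21.7%) had an unadjusted p below 0.05, against 19.1% of all 11676 genes tested (one-sided Fisher exact p = 0.454). Chance and a change across the family cannot be told apart with so few members.

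Same-numbered libraries of the groups deviated together, and X and Y genes were tested as the whole cause. Without those genes the correlation of deviations was 0.179, which argues against it.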
